A study of Homo sapiens with 12 samples.

How the data were processed

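The series holds 12 Illumina BeadChip arrays of Raji cells. The authors deposited a table of raw values in which, per the file headers, each array has a column of signal and a column of detection p-values. The deposited raw signal is an intensity on a linear scale, the mean brightness of a probe's beads, with no normalization and no background subtracted. The detection p-value of a probe, per the file headers, is given for every array. The authors also deposited processed values, which are intensities on a linear scale normalized between arrays. After the tables were joined by their values, as described below, the processed values of an array ordered the probes almost as the raw values did. The lowest rank correlation was 0.999902, and because the join used the ranks, this value is in part built in. The distributions of the processed values were nearly shared among the 6 arrays of each naming set and differed between the sets. The authors' normalization was therefore made separately for each set. The image reading and processing software is not given in the sources used here.

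The raw table names its probes by another identifier than the processed table and the probe annotation. The raw and processed tables were therefore joined by their values, by matching each probe's profile over the 12 arrays. All 48107 probes matched uniquely, with a largest distance of 0.0494 to the matched probe and a smallest distance of 0.076 to any other. The 2 missing values in each table fell on the same probes and arrays, which left 48105 probes with complete values. Gene symbols came from the probe annotation given with the series and were joined by probe identifier. Of the probes, 30113 carried 1 symbol, 8 carried several and were not named, and 17986 carried none. No symbol was replaced by a newer name.

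Background was corrected and values were quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, with the distribution of background inferred from the detection p-values and an offset of 16. A probe was kept if its detection p-value was under 0.05 on at least 2 arrays, which left 27789 probes, 18649 of them with 1 symbol. Each gene was represented by its probe with the highest mean, which gave 13702 genes. limma's linear model and empirical Bayes test with an intensity trend were fitted to all 12 arrays together, two-sided, with Benjamini-Hochberg adjustment over the 13702 genes and a threshold of 0.05. All adjusted p-values for genes come from this limma model, and errors written after ± are standard errors from it unless given as SD. The groups were shCREM, shMS4A1, shMBD2_A, shMBD2_C and shNTC. The naming set was a block: set 1 holds the labels without a replicate number and set 2 those with a number. Because only shNTC has arrays in both sets, shMS4A1 and shCREM are in effect compared with 1 shNTC array, and shMBD2 with 2. The effect of shMBD2 is the mean of its hairpins A and C. For a gene detected on none of the arrays on 1 side of a comparison, a lower bound of the fold is given with the words "at least". It sets the mean log2 level of the other side against the mean, over the undetected arrays, of the gene's own level or the lowest level of any detected probe on that array, whichever was higher.

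The 32 gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the lists of a comparison. Of 754 list entries 622 were measured, which covers 593 of 720 distinct genes. The camera test was repeated with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance in 1 direction, was also run. A count "adjusted over the list alone" applies the adjustment to the measured members of that list.

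The tests, the groups, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule names the targeted gene and MS4A1, then up to 10 genes with the largest change in each direction among those that passed and moved that way on every array of the group. The direction on an array was taken against the mean of the arrays it was compared with. For genes named by size of change, agreement of all arrays in direction was a condition of being named and is no separate support. Where fewer than 10 passed in total, genes with the smallest p-values were added and are given as values that did not pass. For differences between hairpins or targets the rule takes 5 genes each way, and for each list described up to 4 members with the smallest p-values. The list tests for the difference between shCREM and shMS4A1, the fits without an array of a group outside the comparison, and the classes of replication-dependent histone and short non-coding RNA genes, were chosen after seeing the data. Those RNA classes were drawn from gene symbols and from the gene types of a human annotation (GRCh38.p14). That annotation was used only for names and gene types, and no genome positions were used.

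The model was tried on simulated arrays with the same design, in which 67 genes of 13702 were given a log2 change of 0.5, 67 a change of 1 and 66 a change of 2. Of genes given a log2 change of 1, the test found 37.3% in the shMS4A1 comparison, 22.4% in the shCREM comparison and 82.1% in the shMBD2 comparison. For a log2 change of 2 the shares were 97%, 90.9% and 100%. In the single-hairpin comparisons for MBD2 the shares at a log2 change of 1 were 53.7% and 58.2%, and in the difference between shCREM and shMS4A1 the share was 76.1%.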

Results

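Gene expression was measured on 12 Illumina BeadChip arrays in Raji cells, an established human Burkitt lymphoma B cell line that carries CD20. CD20 is the protein made by MS4A1 and the target of therapeutic antibodies such as rituximab. The cells had been transduced with short hairpin RNAs (shRNAs) and selected with puromycin for 48 h, and total RNA was taken 3 days after transduction. The hairpins were directed against MS4A1 itself (3 arrays, hairpins A, B and C) or CREM, a cAMP-responsive transcription factor (2 arrays, hairpins A and B). Others were directed against MBD2, a reader of methylated DNA in the NuRD repressor complex (2 arrays each for hairpins A and C). The control was a non-targeting hairpin, shNTC (3 arrays). The labels fall into 2 naming sets of 6 arrays. Set 1 holds the shMS4A1 and shCREM arrays with shNTC replicate 3, and set 2 holds the shMBD2 arrays with shNTC replicates 1 and 2. Median raw intensity was 99.15 to 104.87 in set 1 and 76.92 to 86.81 in set 2. Between 18652 and 20483 of 48105 probes were detected on an array, with the lowest number on shNTC replicate 1. Between the shNTC arrays of set 2 and set 1, 869 genes differed (limma, adjusted p under 0.05, 346 higher and 523 lower in set 2). Set 1 has 1 shNTC array, so this difference rests on that array, with the spread taken from the other groups. Each knockdown was compared with the shNTC of its own set. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples only. That spread is shared by all groups. It mixes differences between hairpins (shMS4A1 and shCREM) with differences between repeats of 1 hairpin (shMBD2_A, shMBD2_C and shNTC of set 2). The p-values for shMBD2 take no account of differences between hairpins A and C. The small number of arrays limits the precision.

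The series title places the study in the regulation of CD20, so the level of MS4A1 and of each targeted gene came first. MBD2 fell under shMBD2 by 1.77 ± 0.24 log2 (ILMN_1750395, 3.41-fold, n = 4 against 2, limma adjusted p = 0.00105, lower on 4 of 4 arrays). Of the other MBD2 probes, ILMN_1717195 was detected on 2 arrays, ILMN_2387452 on 1 and ILMN_1785587 on 0. MS4A1 rose under shMBD2 by 0.99 ± 0.24 log2 at its brighter probe (ILMN_1776939, 1.98-fold, limma adjusted p = 0.0362, higher on 4 of 4 arrays). At a second probe, ILMN_2401714, the value was 0.52 log2 and did not pass (limma adjusted p = 0.242). The alternatives were fitted for ILMN_1776939 only. Over these and the other probes, limma adjusted p for MS4A1 under shMBD2 ran from 0.0213 to 0.704. MS4A1 under its own hairpins had a value of -1.17 ± 0.32 log2 at ILMN_1776939 (2.25-fold, n = 3 against 1, limma adjusted p = 0.29, lower on 3 of 3 arrays), which did not pass. At ILMN_2401714, which was not followed through the alternatives, it fell by 1.93 log2 (3.82-fold, lower on 3 of 3 arrays, limma adjusted p = 0.0149). Over the alternatives for ILMN_1776939 and the other probes, limma adjusted p ran from 0.0149 to 0.998. The direct contrast of shCREM with shMS4A1, which needs no control array, put MS4A1 2.04 ± 0.25 log2 higher under shCREM (4.1-fold, n = 2 against 3, limma adjusted p = 0.000364, 2 of 2 arrays). Against shNTC, MS4A1 under shCREM had a value of 0.86 ± 0.34 log2 (1.82-fold, n = 2 against 1, limma adjusted p = 0.51, higher on 2 of 2 arrays), which did not pass. CREM has 1 probe, ILMN_1745318, which was detected on 4 of the 12 arrays. It was undetected on both shCREM arrays, at least 1.53-fold below its shNTC array, with a value of -0.74 ± 0.30 log2 that did not pass (limma adjusted p = 0.528, lower on 2 of 2 arrays). CREM stood at 5.1 log2 on that shNTC array and was undetected, at 4.25 and 4.47, on shNTC replicates 1 and 2. The value thus rests on 1 control array near background. Against the same shNTC array CREM had a value of -0.51 ± 0.29 log2 under shMS4A1 (adjusted p = 0.926), and in the direct contrast it was -0.23 ± 0.23 under shCREM (adjusted p = 0.642), neither of which passed. The third MS4A1 probe, ILMN_1697830, was detected on 3 arrays only. The rise of MS4A1 under shMBD2 lost its call when shNTC replicate 2 was left out (0.55 log2, adjusted p = 0.189). It was also lost without shMBD2_A replicate 1 (0.117) or 2 (0.0843) and without shMBD2_C replicate 1 (0.0928) or 2 (0.127). It kept the call without shNTC replicate 1 (1.42 log2, adjusted p = 0.0347). Arrays of other groups enter through the shared spread, and in fits chosen after seeing the data the call was lost without shMS4A1 hairpin A (0.052), B (0.0551) or C (0.06) and kept without shCREM hairpin A (0.0278) or B (0.028).

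**Figure D1:**
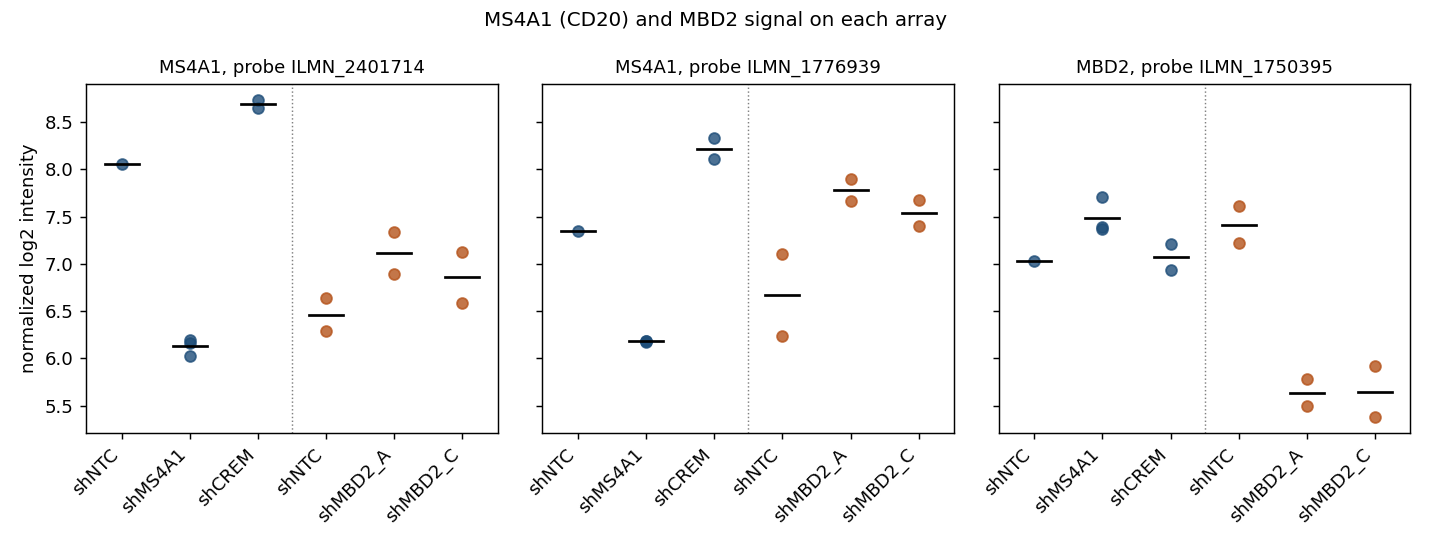
Normalized log2 intensity of MS4A1 at probes ILMN_2401714 and ILMN_1776939 and of MBD2 at ILMN_1750395, with 1 point per array, bars at group means, and a dotted line between the naming sets. MBD2 is lowest on the 4 shMBD2 arrays (5.38 to 5.92, against 7.22 and 7.61 on the shNTC arrays of that set), and the brighter MS4A1 probe lies at 6.17 to 6.19 under shMS4A1 and at 8.11 and 8.33 under shCREM.

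The comparison of shMS4A1 with shNTC asks which genes change when CD20 itself is depleted. Targets of NF-kB and of interferon were among the genes that fell. CCR7, a receptor that guides lymphocytes to lymph nodes, fell 5.42-fold (-2.44 ± 0.24 log2, n = 3 against 1, limma adjusted p = 0.000282, lower on 3 of 3 arrays). CXCL10, an interferon-induced chemokine, fell 7.72-fold (-2.95 ± 0.41, adjusted p = 0.00872, 3 of 3). TRAF1 (-2.20 ± 0.34, adjusted p = 0.0149), which acts downstream of TNF receptors, and LTA, the cytokine lymphotoxin alpha (-1.63 ± 0.21, adjusted p = 0.0041), fell on 3 of 3 arrays. So did BCL2, an inhibitor of apoptosis (-1.57 ± 0.24, adjusted p = 0.0122). MIR155HG, the host gene of the B cell microRNA miR-155, fell by 2.10 ± 0.35 log2 (adjusted p = 0.0221, 3 of 3). In all, 27 of 13702 genes changed, 5 higher and 22 lower.

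The other genes named among the lower were EBI3, a subunit of the cytokines IL-27 and IL-35 (-2.45 log2), SLAMF1, a lymphocyte surface receptor (-2.44), RGS1, a regulator of chemokine receptor signalling (-2.22), LINC00158 (-2.18), and the interferon-induced IFIT3 (-2.06) and IFIT2 (-2.03). Their limma adjusted p ran from 0.0111 to 0.037, with lower values on 3 of 3 arrays each, as the naming rule required. The 5 genes that rose were ACTL8 (at least 2.93-fold, undetected on the shNTC array), HMCES, which protects abasic sites in DNA (1.55 ± 0.27 log2), DEF8 (1.41 ± 0.26), ABR (1.21 ± 0.23), and MME, the germinal centre marker CD10 (1.05 ± 0.20). Their adjusted p ran from 0.0236 to 0.0482, with higher values on 3 of 3 arrays each, as the naming rule required. Without the control array, 19 of the 22 genes that fell were also lower under shMS4A1 than under shCREM, and 3 of the 5 that rose were also higher (limma). The same 3 shMS4A1 arrays had chosen these genes, so part of this agreement was built in.

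Of the NF-kB target list, 4 of 23 measured members fell (LTA, CXCL10, TRAF1 and EBI3), 0 rose and 19 did not pass. Adjusted over the list alone 9 fell. The list median was -0.68 log2, below 0 on 3 of 3 arrays (camera adjusted p = 6.92e-17), with adjusted p = 0.0836 with an estimated correlation, the highest of its alternatives. Of the interferon response list, 3 of 25 members fell (CXCL10, IFIT3 and IFIT2), 0 rose and 22 did not pass, with 12 lower when adjusted over the list alone. The median was -0.65 log2, below 0 on 3 of 3 arrays (camera adjusted p = 7e-13, and adjusted p = 0.0231 with an estimated correlation, over all alternatives 6.07e-15 to 0.152). MHC class II genes, which present antigen to helper T cells, had values below 0 for 14 of 14 members, such as HLA-DOA (-0.99 ± 0.22 log2) and HLA-DPA1 (-0.69 ± 0.16). None of the 14 passed over all genes (845 genes of the 13702 had an unadjusted limma p under 0.05), and 7 fell when adjusted over the list alone. The median was -0.57 log2, below 0 on 3 of 3 arrays (camera adjusted p = 1.64e-12, and adjusted p = 0.0231 with an estimated correlation, the highest of its alternatives). B cell surface genes had a median of -0.44 log2 on 3 of 3 arrays. SLAMF1 fell among 27 members and 26, the targeted MS4A1 among them, did not pass. Adjusted over the list alone 3 rose and 10 fell (camera adjusted p = 7.16e-05, and adjusted p = 0.226 with an estimated correlation, the highest of its alternatives). Cholesterol synthesis genes had a median of -0.39 log2 on 20 members. None passed over all genes or adjusted over the list alone (camera adjusted p = 0.000126, and adjusted p = 0.226 with an estimated correlation, over all alternatives 3.57e-05 to 0.304). The other 5 of the 10 lists that camera called were close to the threshold, with adjusted p of 0.0439 to 0.0474 and adjusted p of 0.226 to 0.755 with an estimated correlation (over all alternatives 8.1e-08 to 0.791). Without hairpins A, B and C 8, 6 and 6 lists were called, and without hairpin B the NF-kB target median was -0.45 log2. Markers of T and NK cells, myeloid cells, and epithelial cells and fibroblasts were not called by camera in any of the 5 comparisons for which lists were tested.

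The count of 27 rests on 1 control array, and left out singly, hairpin A gave 17, hairpin B 8 and hairpin C 7. Of the 10 named falls 7, 3 and 3 and of the 5 rises 0, 1 and 0 were then still called. CCR7 and CXCL10 were called each time, but TRAF1 and MIR155HG not without B (adjusted p = 0.0626 and 0.0763) or C (0.0651 and 0.0844). Fitted with no set block the count was 235, with 13 genes in common, and within set 1 alone it was 1. Arrays of other groups set part of the spread. In fits chosen after seeing the data the count was 46 and 47 without shCREM hairpin A or B, 10 without either shMBD2_A array and 17 without either shMBD2_C array. Of the 10 named falls 5 and of the 5 rises 0 were still called without either shMBD2_A array, and 9 and 1 without either shMBD2_C array.

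The comparison of shCREM with shNTC asks what CREM depletion does to MS4A1 and to the cell's programme. Genes of DNA replication and mitosis were lower as lists by camera, with adjusted p = 0.263 for both lists with an estimated correlation, the highest of their alternatives. None of them passed alone. CCNA2, the S and G2 phase cyclin A2, had a value of -1.27 ± 0.21 log2 (2.41-fold, n = 2 against 1, limma adjusted p = 0.0785, lower on 2 of 2 arrays). MCM5, a subunit of the replicative helicase, had a value of -1.15 ± 0.22 (adjusted p = 0.103, 2 of 2). Over 30 measured G2/M genes the median was -0.68 log2, with 30 of 30 values below 0. Over 25 G1/S genes it was -0.63 log2, with 24 below 0, on 2 of 2 arrays each. INSIG1, which restrains sterol synthesis, had a value of -1.88 ± 0.33 log2 (adjusted p = 0.0794, 2 of 2). CCNA2 passed without shNTC replicate 1 (limma adjusted p = 0.0352) or 2 (0.0343), and INSIG1 was at -1.24 log2 without hairpin B. shNTC replicates 1 and 2 lie in set 2 and enter this comparison only through the shared spread. The pass of CCNA2 is therefore no gain in support. A fit without a hairpin sets 1 shCREM array against 1 shNTC array. It loses the spread between the hairpins (SD 0.91 for INSIG1), so its gene calls are not given. The highest limma adjusted p over all alternatives was 0.359 for CCNA2 and 0.437 for INSIG1.

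DMRTC2 was the single gene to pass (1 of 13702, with 1140 at an unadjusted limma p under 0.05). It fell at least 3.32-fold (limma adjusted p = 0.0105, n = 2 against 1, lower on 2 of 2 arrays). Its level was 6.21 on the shNTC array of set 1 and 4.24 to 4.66 on all other arrays, the other shNTC arrays included. The next genes by p did not pass. These were RAB22A (-1.49 log2), GPD1L (-1.11), PVRIG (-1.52), PARPBP (-1.42) and IMPA2 (-1.23), with lower values on 2 of 2 arrays. Higher on 2 of 2 were ST3GAL6 (at least 2.76-fold higher) and DBNDD2 (2.09). Adjusted p for these 7 genes ran from 0.0785 to 0.103. RAB22A, GPD1L, PVRIG, IMPA2 and DBNDD2 passed without shNTC replicate 1 or 2. These shNTC arrays enter this comparison only through the shared spread, so the passes are no gain in support. Calls of genes from fits with 1 shCREM array are not given.

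In the G2/M list 0 of 30 members passed over all genes and 15 fell when adjusted over the list alone (camera adjusted p = 1.71e-16, and adjusted p = 0.263 with an estimated correlation, the highest of its alternatives). In the G1/S list 0 of 25 passed and 9 fell when adjusted over the list alone (camera adjusted p = 1.04e-14, and adjusted p = 0.263 with an estimated correlation, the highest of its alternatives). B cell surface genes had a median of 0.26 log2 on 27 members, above 0 on 2 of 2 arrays. None passed over all genes and 0 did adjusted over the list alone (camera adjusted p = 0.000876, and adjusted p = 0.263 with an estimated correlation, over all alternatives 0.000125 to 0.294). Among them, CD37 had a value of 0.71 ± 0.23 log2 and CD86, a costimulatory ligand, of 0.86 ± 0.30, higher on 2 of 2 arrays each. Targets of MYC had a median of -0.20 log2 on 28 members and cholesterol synthesis genes of -0.25 on 20. None passed over all genes, and 0 and 1 fell when adjusted over the list alone (camera adjusted p = 0.00224 and 0.00234, and adjusted p = 0.263 with an estimated correlation for both, over all alternatives 0.000193 to 0.794 and 0.000552 to 0.44). Without the set block the MYC target median was 0.07 log2. Genes known as targets of CREB and CREM had a median of -0.02 log2 on 22 members and were not called (camera adjusted p = 0.8, 0 past the test over all genes and 0 adjusted over the list alone). The other 3 called lists had camera adjusted p of 0.0361 to 0.0493, and adjusted p of 0.263 to 0.338 with an estimated correlation (over all alternatives 0.00499 to 0.617). The B cell surface call was lost without hairpin A (adjusted p = 0.0691) and the MYC target call without hairpin B (0.101), while the G2/M and G1/S calls held without either. The G2/M median was -0.39 log2 without hairpin A, and the B cell surface median 0.46 without hairpin B. Each fit without a hairpin set 1 shCREM array against 1 shNTC array. The difference between the hairpins was then no part of the spread, so a higher count of genes there is no gain in support. The count of 1 became 9 without shNTC replicate 1 or 2, which enter this comparison only through the shared spread. With no set block it was 240, without DMRTC2.

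**Figure D2:**
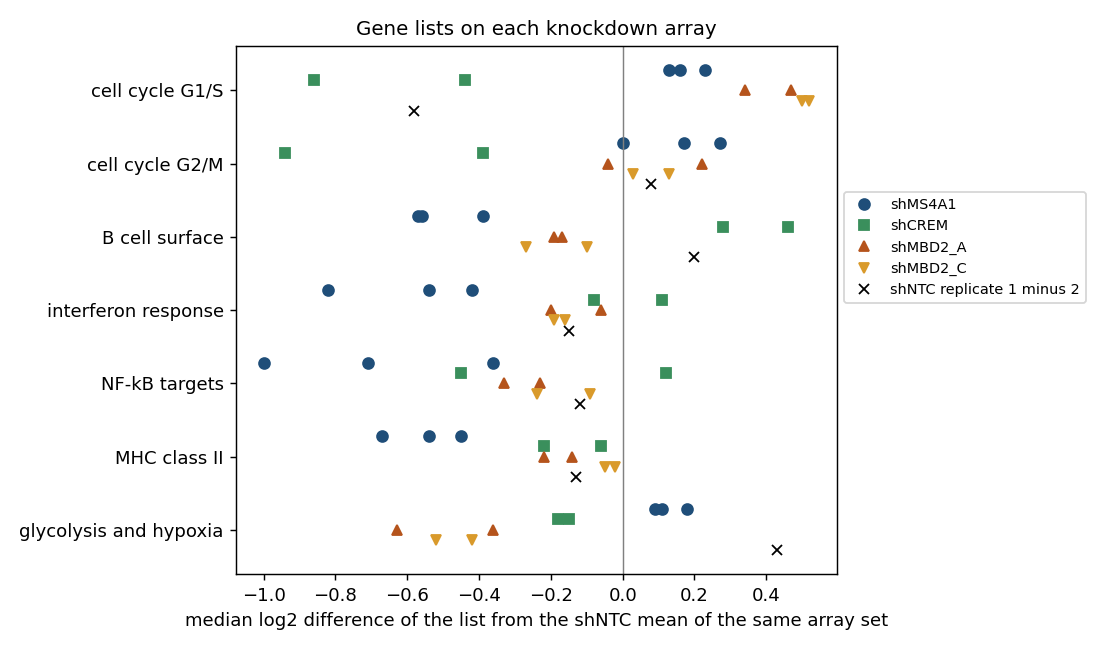
Median log2 difference of 7 gene lists from the mean of the shNTC arrays of the same naming set, with 1 symbol per array and crosses for shNTC replicate 1 minus replicate 2. The G1/S and G2/M medians are lowest on the shCREM arrays (-0.39 to -0.94), interferon response genes lie at -0.42 to -0.82 on the shMS4A1 arrays, and the G1/S and glycolysis and hypoxia medians differ between the shNTC replicates by -0.58 and 0.43.

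The direct contrast of shCREM with shMS4A1 compares both knockdowns without a control array and asks where they differ. RGS1 was 8.26-fold higher under shCREM (3.05 ± 0.26 log2, n = 2 against 3, limma adjusted p = 1.47e-05, 2 of 2 arrays). SLAMF1 was 8.25-fold higher (3.04 ± 0.32, adjusted p = 0.000124, 2 of 2). CD86 was higher by 1.66 ± 0.23 log2 (adjusted p = 0.000603, 2 of 2), and TRAF1 by 2.11 ± 0.27 (adjusted p = 0.000419, 2 of 2). Of 30 G2/M genes 16 were lower under shCREM and 14 did not pass, and of 25 G1/S genes 14 were lower and 11 did not pass, with adjusted p = 0.168 for both lists with an estimated correlation, the highest of their alternatives. Among them were CCNA2 (-1.60 ± 0.16 log2, adjusted p = 7.51e-05, 2 of 2 arrays), RRM2, a subunit of ribonucleotide reductase (-1.98 ± 0.29, adjusted p = 0.00114, 2 of 2) and PLK1, a mitotic kinase (-1.37 ± 0.22, adjusted p = 0.00186, 2 of 2). In all, 839 of 13702 genes differed, 393 higher and 446 lower under shCREM.

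The largest differences upward also included ADAMDEC1 (2.88 ± 0.38 log2), the histone gene H2BC12 (2.88 ± 0.29) and FCRL4, an Fc receptor-like protein of memory B cells (2.87 ± 0.29). ADAMDEC1 and FCRL4 were each detected on 1 of 3 shMS4A1 arrays, so the sizes of their differences rest on levels near background. Their limma adjusted p ran from 7.51e-05 to 0.000504. Downward they included CDKN3 (-2.38 ± 0.57, adjusted p = 0.0225, with an SD of 2.42 between the shCREM hairpins). The histone genes H2BC7 (-2.12 ± 0.28, detected on 1 of 2 shCREM arrays) and H3C8 (-1.99 ± 0.28), and NMU (-1.98 ± 0.29) were lower as well, with adjusted p of 0.000531 to 0.00114. Each of these genes differed in the same direction on 2 of 2 arrays, as the naming rule required. Of 30 G2/M genes 16 were lower and of 25 G1/S genes 14, with 24 and 21 adjusted over the list alone and 0 higher in either. Their medians were -0.81 and -0.83 log2 (camera adjusted p = 2.36e-19 and 1.19e-17, and adjusted p = 0.168 with an estimated correlation for both, the highest of their alternatives). Of 27 B cell surface genes 12 were higher and 1 lower (CD38), with 14 and 1 adjusted over the list alone. The 12 include MS4A1, the gene that shMS4A1 targets. Their median was 0.68 log2 (camera adjusted p = 3.18e-09, and adjusted p = 0.101 with an estimated correlation, the highest of its alternatives). Interferon response genes (9 of 25 higher, 13 adjusted over the list alone, median 0.58 log2), NF-kB targets (8 of 23, 12 adjusted over the list alone, 0.60) and MHC class II genes (4 of 14, 8 adjusted over the list alone, 0.48) had 0 lower members past the test. All 3 were called by camera (adjusted p = 4.35e-09, 5.45e-08 and 9.19e-06, and adjusted p = 0.101, 0.168 and 0.101 with an estimated correlation, the highest of their alternatives). Camera called 4 more lists: MYC targets (1 of 28 lower, 4 adjusted over the list alone, median -0.24 log2), glycolysis and hypoxia genes (1 of 30 higher and 4 lower, 1 and 8 adjusted over the list alone, -0.26), the MS4A family (1 of 5 higher, the targeted MS4A1 itself, 1 adjusted over the list alone, 0.49) and the unfolded protein response (0 of 22, 0 adjusted over the list alone, 0.19). Their adjusted p were 0.000145, 0.00148, 0.00249 and 0.00885, and adjusted p = 0.123, 0.399, 0.108 and 0.304 with an estimated correlation, the highest of their alternatives. Examples from the interferon, NF-kB and MHC class II lists are, in that order, IFIT2 (2.48 ± 0.30 log2), CCL3, a chemokine (2.26 ± 0.33), and HLA-DQB1 (1.38 ± 0.26). The list tests in this contrast were chosen after its count of genes had been seen. CDKN3 lost its call without shCREM hairpin A (-0.67 log2, adjusted p = 0.0519). It also did without shMS4A1 hairpins A (0.0561), B (0.0666) or C (0.0795), and HLA-DQB1 without shCREM hairpin A (0.0781). CDKN3 was at -4.09 log2 without shCREM hairpin B, and CD38 lost its call without either shCREM hairpin, shMS4A1 hairpins A or C, or any 1 of the shMBD2 arrays. Without shCREM hairpin A the medians were 0.33 log2 for B cell surface genes, 0.36 for NF-kB targets, 0.81 for the MS4A family and 0.32 for the unfolded protein response. The last 2 lost their calls without shCREM hairpin B (0.23 log2, adjusted p = 0.0564, and 0.12 log2, adjusted p = 0.288). The count fell to 496 without shCREM hairpin A and to 532, 421 and 406 without shMS4A1 hairpins A, B and C. It was 330 with no set block and 350 within set 1 alone. With median scaling the split was 321 higher and 618 lower.

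Log2 changes under shCREM and shMS4A1 correlated across genes with r = 0.335, where unchanged groups sharing a control array gave 0.706 in 100 simulations, and genes are not independent replicates. Their covariance was 0.0424, against 0.0676 in the simulations, a difference of -0.0253. The simulations gave all arrays the same spread, though the shCREM arrays differed more (SD of log2 difference 0.473) than the shMS4A1 arrays (0.356 to 0.376). DMRTC2 was the 1 gene that fell under both, against 0.02 in the simulations and 0.00161 from independent lists. Its level stood out on the shared shNTC array (6.21, against 4.24 to 4.66 on the other 11 arrays), so this overlap follows that array.

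The comparison of shMBD2 with shNTC asks what loss of MBD2 does to MS4A1 and to other genes. Of 30 listed genes of glycolysis and the response to low oxygen 11 fell and 19 did not pass, and the list's call by camera was lost with an estimated correlation (adjusted p = 0.255, the highest of its alternatives). HILPDA, a hypoxia-induced lipid droplet protein, fell 6.79-fold (-2.76 ± 0.19 log2, n = 4 against 2, limma adjusted p = 1.28e-06, lower on 4 of 4 arrays). The glucose transporter SLC2A1 fell 3.98-fold (-1.99 ± 0.23, adjusted p = 0.00041, 4 of 4), and the hexokinase HK2 fell by 1.67 ± 0.16 log2 (adjusted p = 0.000107, 4 of 4). Of 59 replication-dependent histone genes 12 rose and of 248 short non-coding RNA genes 29, classes chosen after the data were seen, and 2 of these 41 were still called without shNTC replicate 1. The largest rise was that of RNU6ATAC, an RNA of the minor spliceosome (5.60-fold, 2.48 ± 0.33 log2, adjusted p = 0.00102, 4 of 4). The histone gene H4C2 rose 4.99-fold (2.32 ± 0.31, adjusted p = 0.00102, 4 of 4). In all, 392 of 13702 genes changed, 213 higher and 179 lower.

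Others among the 10 largest falls were BHLHE40, a transcriptional repressor (-2.94 ± 0.35 log2, 7.68-fold, detected on 1 of 4 shMBD2 arrays), ANKRD37 (-2.53 ± 0.30), DDIT4, an inhibitor of mTORC1 (-2.13 ± 0.26), and RGS1 (-2.08 ± 0.25). Next came HINT3 (-2.06 ± 0.25), the kinase ROCK1 (-1.99 ± 0.27), EGLN1, an oxygen-sensing prolyl hydroxylase (-1.82 ± 0.29), and the glucose transporter SLC2A3 (-1.80 ± 0.27). Their limma adjusted p ran from 0.00041 to 0.00324, with lower values on 4 of 4 arrays each, as the naming rule required. Others among the 10 largest rises were TMEM107 (2.18 ± 0.28), the vault RNA VTRNA1-1 (2.00 ± 0.36) and the histone genes H2BC8 (1.95 ± 0.34), H3C7 (1.75 ± 0.36) and H2AC12 (1.72 ± 0.26), the last 2 detected on 1 of 2 shNTC arrays. The rest were the metallothionein MT1X (1.81 ± 0.37), FAM111A, a protease of replicating cells (1.73 ± 0.24), and RNU4-1, a small nuclear RNA (1.71 ± 0.31). Their adjusted p ran from 0.000892 to 0.0157, with higher values on 4 of 4 arrays each, as the naming rule required. The shNTC arrays of this set differed widely for BHLHE40 and MT1X (SD 1.17 each) and for H3C7 (SD 1.22).

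**Figure D3:**
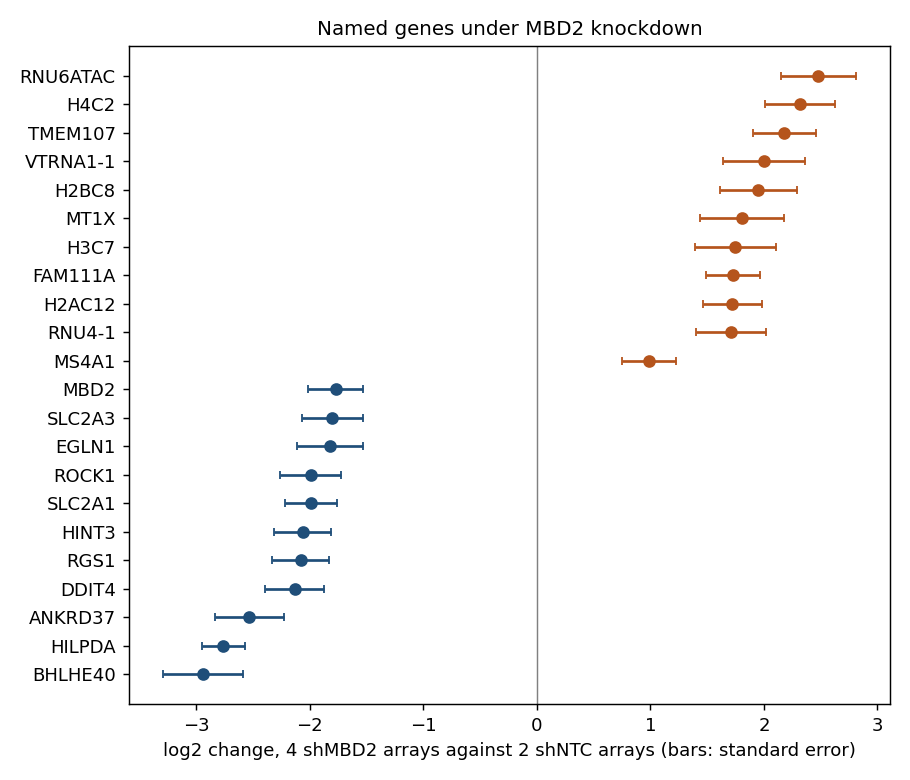
Log2 change of the named genes in 4 shMBD2 arrays against 2 shNTC arrays, with points for limma estimates and bars for standard errors. Values run from -2.94 for BHLHE40, detected on 1 of 4 shMBD2 arrays, to 2.48 for RNU6ATAC, with MS4A1 at 0.99 and MBD2 at -1.77.

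Of the glycolysis and hypoxia list, 11 of 30 members fell, 0 rose and 19 did not pass, and 19 fell when adjusted over the list alone. Among them were HK2, SLC2A1, ANKRD37 and DDIT4. The median was -0.46 log2, below 0 on 4 of 4 arrays (camera adjusted p = 6.44e-18), and adjusted p = 0.255 with an estimated correlation was the highest of its alternatives. In the G1/S list MCM5 (0.71 ± 0.16 log2), FEN1, a replication nuclease (1.00 ± 0.22), and CDT1, a licensing factor (0.81 ± 0.19), rose among 25 members, with 13 higher and 2 lower when adjusted over the list alone. The median was 0.45 log2, above 0 on 4 of 4 arrays (camera adjusted p = 3.54e-06, and adjusted p = 0.69 with an estimated correlation, the highest of its alternatives). Of the ATF4 stress list 3 of 29 members fell (DDIT4, CEBPB and SLC38A2), 4 adjusted over the list alone. The median was -0.24 log2 (camera adjusted p = 0.000582, and adjusted p = 0.69 with an estimated correlation, over all alternatives 6.38e-09 to 0.969). Among 27 B cell surface genes MS4A1 rose and 4 fell. These were CD79A, a signalling chain of the B cell receptor (-0.87 ± 0.13 log2, adjusted p = 0.00225), SLAMF1 (-1.60 ± 0.31, adjusted p = 0.0113), CD48 (-0.59 ± 0.15, adjusted p = 0.0452), each lower on 4 of 4 arrays, and TNFRSF13C, the BAFF receptor (-1.49 ± 0.38 log2, adjusted p = 0.0474, not followed through the alternatives). Adjusted over the list alone 3 rose and 7 fell, with a median of -0.21 log2 (camera adjusted p = 0.0173, and adjusted p = 0.69 with an estimated correlation, the highest of its alternatives). Genes of B cell receptor signalling had a median of -0.20 log2 on 21 members. None passed over all genes or adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.69 with an estimated correlation, the highest of its alternatives). Of 22 CREB and CREM targets 2 fell (NFIL3 and PPP1R15A), 3 adjusted over the list alone. The median was -0.21 log2 (camera adjusted p = 0.0263, and adjusted p = 0.565 with an estimated correlation, the highest of its alternatives). The interferon list (1 of 25 fell, IFIH1, and 2 adjusted over the list alone, median -0.15 log2) and the histone list (1 of 19 rose, H2BC14, and 4 adjusted over the list alone, median 0.29) were called by camera at adjusted p = 0.0488 each. They had adjusted p = 0.69 with an estimated correlation, the highest of their alternatives.

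The control arrays carried much of the number of calls. Leaving out 1 of the 2 shNTC arrays of this set also removes the spread between them (SD of their log2 difference 0.457). A higher count in such a fit is therefore no gain in support. Without shNTC replicate 1, which had the fewest detected probes and whose median correlation with the other arrays of its set was 0.974, 33 genes were called, and without replicate 2 there were 1062. Without shMBD2_A replicate 1 or 2 there were 165 and 133, and without shMBD2_C replicate 1 or 2 there were 131 and 124. Without shNTC replicate 1, 9 of the 10 named falls kept their call (all but EGLN1) and 2 of the 10 named rises did (TMEM107 and MT1X). RNU6ATAC (2.15 log2, adjusted p = 0.0553) and H4C2 (2.03, adjusted p = 0.0528) lost theirs. So did the list members CD79A (-0.70, adjusted p = 0.0753), SLAMF1 (-1.81, adjusted p = 0.0926), CD48 (-0.34, adjusted p = 0.486), MCM5 (0.45, adjusted p = 0.302), FEN1 (0.40, adjusted p = 0.357) and CDT1 (0.58, adjusted p = 0.348). H3C7, CD48, MCM5, FEN1 and CDT1 also lost their calls without any 1 of the 4 shMBD2 arrays. IFIH1, PPP1R15A and H2BC14 lost theirs without any 1 of these or shNTC replicate 1 (adjusted p = 0.243, 0.423 and 0.388). SLAMF1 lost its call without shMBD2_A replicate 2, shMBD2_C replicate 2 or shNTC replicate 2, and MT1X without these or shMBD2_C replicate 1. Calls for NFIL3, CEBPB and SLC38A2 ended without shNTC replicate 1 (0.402, 0.301 and 0.245) and without 1 or more of the shMBD2 arrays, and that for SLC38A2 also without shNTC replicate 2 (0.0791). Values without shNTC replicate 1 were 0.89 log2 for H3C7, -0.45 for PPP1R15A and -0.58 for CEBPB. Without replicate 2 they were 0.99 for MT1X, -2.43 for PPP1R15A and 1.60 for FEN1. The camera calls for the B cell surface (median -0.09 log2, adjusted p = 0.235), CREB and CREM target (-0.13, 0.0546), G1/S (0.18, 0.298), ATF4 (0.07, 0.969) and histone (0.32, 0.168) lists were lost without shNTC replicate 1. The ATF4 median thus turned, from -0.24 log2, though camera's direction stayed down. Without replicate 2 the calls lost were those for B cell receptor signalling (0.207), CREB and CREM targets (0.0697), interferon response (0.597) and histones (0.158, median 0.50 log2), while the G1/S median was 0.84 and the ATF4 median -0.64. Between the shNTC replicates, 1 minus 2, these 2 medians differed by -0.58 and 0.62 log2. Without shMBD2_A replicate 2 the CREB and CREM target (0.0846) and histone (0.135) calls were lost, and without shMBD2_C replicate 1 the histone call (0.0977). The interferon call was lost without shMBD2_A replicate 1 (0.104) or shMBD2_C replicate 2 (0.113). The glycolysis and hypoxia call held without either shNTC array (median -0.34 and -0.69 log2). With no set block 38 genes were called, all among the 392, and 5 of the 10 named falls and 2 of the 10 named rises kept their calls. In fits chosen after seeing the data, with an array of another group left out, the count was 708 without shCREM hairpin A or B and 309, 300 and 262 without shMS4A1 hairpins A, B and C. Without any 1 of these shMS4A1 arrays CD48, PPP1R15A and SLC38A2 lost their calls, as CDT1 did without B or C and H2BC14 without A.

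The hairpins against MBD2 were also compared with shNTC singly, to see whether each gave the same changes. Under hairpin A 143 genes changed (68 higher, 75 lower) and under hairpin C 129 (68 higher, 61 lower), with 90 called under both. HILPDA fell by 2.93 ± 0.21 log2 under A (limma adjusted p = 4.5e-06, n = 2 against 2, 2 of 2 arrays) and by 2.60 ± 0.21 under C (adjusted p = 2.62e-05, 2 of 2). BHLHE40 fell at least 7.58-fold under A and by 2.93 ± 0.40 log2 under C, where it was detected on 1 of 2 arrays, so this size rests on levels near background. RNU6ATAC rose by 2.44 ± 0.38 under A and by 2.53 ± 0.38 under C, each on 2 of 2 arrays (adjusted p of 0.0026 to 0.00664). With 1 array of a hairpin left out HILPDA kept its call. BHLHE40 lost it under A (adjusted p = 0.066 and 0.0542) and under C without replicate 1 (0.0769). RNU6ATAC lost it under A (0.147 and 0.0563) and C (0.0861 and 0.104), as it did without shNTC replicate 1 (0.136 and 0.114). MS4A1 had values of 1.11 log2 under A (adjusted p = 0.069) and 0.87 under C (adjusted p = 0.146), higher on 2 of 2 arrays under each, and passed under neither alone. Between the hairpins 0 genes differed (limma, 282 at an unadjusted p under 0.05), and 0 of 32 lists were called by camera. The 282 are fewer than a share of 0.05 of the 13702 genes, which unchanged genes would give on average. The shared spread holds the wider shCREM and shNTC pairs (SD of log2 difference 0.473 and 0.457). The test was thus conservative here, and the lack of calls does not show that the hairpins act alike. The difference, C minus A, was -0.24 log2 for MS4A1 (95% interval -0.83 to 0.34) and 0.01 for MBD2 (-0.58 to 0.60), and over all genes the median interval reached 0.53 log2 to either side. Changes under the hairpins correlated across genes with r = 0.832 against 0.501 in 100 simulations of unchanged groups that share the control arrays, with a covariance of 0.123 against 0.034. With 1 shNTC array for each hairpin, r was 0.371 and 0.366, against 0.0015 in simulations with separate arrays. The hairpins shared 42 genes higher and 48 lower, against 0 and 0.01 in the simulations, 0.337 and 0.334 from independent lists, and 0 in opposite directions. The simulations leave out real effects and independent lists leave out the shared controls, and part of the excess may come from the shared controls. The simulations also gave all arrays the same spread. The shNTC pair differed more (SD of log2 difference 0.457) than the shMBD2_A and shMBD2_C pairs (0.342 and 0.323). The simulated r of 0.501 and covariance of 0.034 are therefore too low as a measure of what shared controls give. The counts for A and C were 14 and 11 without shNTC replicate 1 and 691 and 688 without replicate 2. They were 4 and 9 for A without its replicate 1 or 2, and 3 and 15 for C. In fits chosen after seeing the data, with shCREM hairpin A or B left out, they were 246 and 250 for A and 281 and 283 for C. For A they were 80 and 78 without shMBD2_C replicate 1 or 2, and for C 77 without shMBD2_A replicate 1 or 2.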

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

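Of the tests in this part, 5 were chosen only after the result was seen: that of glycolysis and hypoxia genes under the other hairpins, those of genes that fell under shMS4A1 against shCREM and with a hairpin left out, and both counts of other splits within a naming set. In the difference between shCREM and shMS4A1, 839 genes passed limma's test. MS4A1 differed by 2.04 log2, but shMS4A1 targets this gene, so a difference was built into the contrast. Against shNTC its values were -1.17 log2 under shMS4A1 and 0.86 under shCREM, neither of which passed. Of 9140 probes with no gene symbol, which stand outside the comparisons of genes, 43 were higher and 80 lower under shMBD2 than in the shNTC arrays of the same set (limma, adjusted over these probes), led by ILMN_3240220 (1.85 ± 0.21 log2, adjusted p = 5.1e-05).

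Glycolysis and hypoxia genes had a median of -0.46 log2 under shMBD2. A difference between the control construct and any targeting hairpin would lower them under shCREM and shMS4A1 too. Their median was -0.21 under shCREM, which goes with it, and 0.16 under shMS4A1, which argues against a drop under every targeting hairpin, though with no set block the latter was -0.50. With shNTC replicate 1 left out the median was -0.34 and 7 members instead of 11 fell. Its standard error of 0.16 was taken across the list's genes, as if independent, and holds no error between arrays. The median lay within that error of the bound set for a deviating control array. An effect of MBD2 loss and a state of that 1 control culture therefore cannot be told apart for this list. A difference in oxygen or cell density between cultures stays open and was not tested.

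Histone and short non-coding RNA genes made up 41 of the 213 genes higher under shMBD2, with a median of 1.36 log2 (standard error across genes 0.07). With shNTC replicate 1 left out, their median was 0.99 and 2 of the 41 were still called. With replicate 2 left out instead the median was 1.53, so the calls lean on replicate 1. The 0.99 lay above the bound set for a deviating control array. It cannot decide the question, because the arrays that remain had helped to choose the 41 genes. Over all measured members, called or not, the medians without replicate 1 were 0.28 log2 for short non-coding RNA and 0.35 for histone genes. Over all 248 short non-coding RNA genes measured, the median was 0.30 (standard error across genes 0.04), between the 0.25 and 0.5 set as bounds. Different recovery of short RNAs from the control cultures and a change in the cells therefore cannot be told apart. Errors across genes hold no error between arrays. An effect of MBD2 on these genes may contribute and was not tested apart from this.

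The 22 genes that fell under shMS4A1 were measured against 1 control array, with a median of -1.97 log2. If that array were the source and shCREM left these genes unchanged, they would be as low under shCREM, where their median was -0.08. A rise under shCREM could hide a high level on the control array and was not tested apart from this. With no set block, which brings in the other shNTC arrays, 11 of the 22 were still called lower under shMS4A1. Over the genes that fell with a hairpin left out, that hairpin's median against shCREM was -1.57 (A), -2.55 (B) and -1.61 (C), but these hold only 15, 7 and 7 of the 22 genes, so an off-target effect of 1 hairpin stays open for the others. DMRTC2, and FEZF2 with a level of 6.18 on that control array and at most 4.99 elsewhere, are exceptions that follow the control array. A shared effect of CD20 loss is a hypothesis that these values leave open, and other consequences shared by the 3 hairpins were not tested.

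Other splits of the samples exchanged arrays only within a naming set, with the set block kept. Each other split puts knockdown and control arrays in 1 group, so a real difference would widen the spread and lower the count there. Low counts in the other splits are therefore no support. For shMS4A1, 4 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes (27, with at most 3 in the others). For shMBD2, with its 4 arrays as 1 group, 15 splits are also too few, and 1 split, the real one, gave as many genes (limma, 642, with at most 0 in the others).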

How the results depend on the processing

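The alternatives were set before the data were examined, except the list tests for the difference between shCREM and shMS4A1 and the fits without an array of another group, which were chosen after seeing the data. MBD2 kept its fall at ILMN_1750395 under every alternative fit and with each array left out, and CREM under shCREM did not pass in any. The rise of MS4A1 under shMBD2 and the counts of genes depended on the processing, and except where fewer arrays, another probe or another threshold shows it, the cause was not tested. With no set block, which sets all 3 shNTC arrays against every group, counts of changed genes were 235 (shMS4A1), 240 (shCREM), 38 (shMBD2), 0 (shMBD2_A), 3 (shMBD2_C) and 330 (shCREM against shMS4A1). MS4A1 was then 1.31 log2 higher under shCREM (adjusted p = 0.0363, over its alternatives 0.0363 to 0.791) and 0.76 under shMBD2, and r between shCREM and shMS4A1 changes was 0.549. It also turned 5 list medians, to -0.15 for G2/M, 0.14 for heat shock and -0.50 for glycolysis and hypoxia genes under shMS4A1, and to -0.16 for germinal centre genes and 0.07 for MYC targets under shCREM. Within 1 naming set alone counts were 1 (shMS4A1), 0 (shCREM, limma, against 1140 at an unadjusted p under 0.05 in the full fit) and 350 (shCREM against shMS4A1). With no detection filter counts were 41, 8, 243, 84, 67 and 556 in the order shMS4A1, shCREM, shMBD2, shMBD2_A, shMBD2_C and shCREM against shMS4A1. At an adjusted p under 0.10 they were 41, 8, 889, 288, 359 and 1324. Array weights gave 47 for shMS4A1 and 237 for shMBD2, and no background correction gave 208 for shMBD2_C. For shCREM median scaling gave 17, the deposited processed values 4, every probe 3 and the stricter detection filter 0. MS4A1 under shMBD2 stayed at 0.99 log2 and lost its call within its own set (adjusted p = 0.0741), with no detection filter (0.0645) and with array weights (0.0562), over its alternatives and other probes 0.0213 to 0.704. At other probes MS4A1 had values of 0.52 (ILMN_2401714) and -0.17 (ILMN_1697830) under shMBD2, 0.63 (ILMN_2401714) and -0.37 (ILMN_1697830) under shCREM, and -1.93 (ILMN_2401714) and -0.37 (ILMN_1697830) under shMS4A1. MBD2 had values of -0.10, 0.20 and -0.14 at ILMN_1717195, ILMN_1785587 and ILMN_2387452, which are near background. Lists called were 2 with an estimated correlation, 3 by fry, 5 with median scaling and 6 with a replicate block for shMS4A1. With an estimated correlation and by fry they were 0 and 0 for shCREM, 0 and 1 for shMBD2, and 0 and 9 for shCREM against shMS4A1. With 1 control array for each MBD2 hairpin, r was 0.371 and 0.366. With each array of a comparison left out in turn, the lone array left in a group being assumed to vary like the other groups, counts ranged from 7 to 33 (shMS4A1), 9 to 142 (shCREM), 33 to 1062 (shMBD2), 4 to 691 (shMBD2_A), 3 to 688 (shMBD2_C), 0 to 0 (C minus A) and 406 to 1032 (shCREM against shMS4A1). Log2 values ranged from 0.75 to 0.97 for MS4A1 under shCREM, 0.55 to 1.42 under shMBD2 and -1.18 to -1.17 under shMS4A1, from -0.86 to -0.63 for CREM and from -1.97 to -1.57 for MBD2. Lists called ranged from 6 to 10 (shMS4A1), 6 to 9 (shCREM), 4 to 8 (shMBD2) and 10 to 12 (shCREM against shMS4A1), with 0 for C minus A. Arrays of groups outside a comparison enter through the shared spread. Without shCREM hairpin A or B counts were 46 and 47 (shMS4A1), 708 and 708 (shMBD2), 246 and 250 (shMBD2_A) and 281 and 283 (shMBD2_C). They were 10 and 17 for shMS4A1 without an shMBD2_A or shMBD2_C array, 80 and 78 for shMBD2_A without shMBD2_C replicate 1 or 2, and 77 and 77 for shMBD2_C without shMBD2_A replicate 1 or 2. MS4A1 under shMBD2 lost its call without shMS4A1 hairpin A, B or C (0.99 log2, adjusted p = 0.052, 0.0551 and 0.06). Replicate numbers in set 2 share only a name, since deviations of samples with the same number correlated at -0.0897, -0.0125 and -0.0324. With a replicate block the counts were 20, 1, 316, 120, 89, 0 and 717, with MS4A1 at 0.99 under shMBD2 (adjusted p = 0.0449). No named gene changed sign under any alternative fit. A block for the BeadChip slide was not run, because the columns give no slide, and leaving out the shNTC array of set 1 gave no value for shMS4A1 and shCREM, as no control array would remain there. CREM has no other probe and did not pass the stricter detection filter, and its signal near background limits what these arrays show of its knockdown.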

Other observations

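The RNA classes described here were chosen after the result was seen, and the test of genes lowered under both shMS4A1 and shMBD2 was written before. Under shMBD2, 29 of 248 short non-coding RNA genes rose and 1 fell (Fisher's exact test for the rises, p = 1.59e-17), with a median of 0.30 log2, and of 59 replication-dependent histone genes 12 rose and 0 fell (p = 8.61e-11), with a median of 0.45 log2. Without shNTC replicate 1 these medians were 0.28 and 0.35 log2, and 2 of the 41 rises in these classes were still called. Without replicate 2 the medians were 0.35 and 0.50. Under shMS4A1 the medians were 0.14 and 0.26, and under shCREM 0.04 and -0.09, with 0 genes of either class past limma's test in either comparison (845 and 1140 of all genes at an unadjusted p under 0.05). Between shCREM and shMS4A1, 3 histone genes were higher and 11 lower under shCREM. Genes and classes are not independent, so these p-values do not measure replicate error. As the classes were chosen after these rises were seen, they are no separate evidence for them either.

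Some regulators of apoptosis and stress differed between shCREM and shMS4A1, though camera did not call the apoptosis, heat shock and ATF4 stress lists. Of 21 apoptosis genes 4 were higher (camera adjusted p = 0.0703, fry 0.0198), and of 17 heat shock genes 4 (0.104, fry 0.148), with camera adjusted p = 0.104 for the ATF4 stress list as well. BCL2, an inhibitor of apoptosis, was 1.60 ± 0.19 log2 higher under shCREM than under shMS4A1 (limma adjusted p = 0.000289, n = 2 against 3). PMAIP1, which encodes the pro-apoptotic NOXA, was also higher (1.16 ± 0.21, adjusted p = 0.00507), and the heat shock genes HSPA1B (1.08 ± 0.17, adjusted p = 0.0018) and HSPH1 (0.79 ± 0.14, adjusted p = 0.00482) were higher too. TNFAIP3, an inhibitor of NF-kB, was 2.08 ± 0.34 higher (adjusted p = 0.00253, not followed through the alternatives). Of germinal centre genes in that contrast, SERPINA9 was higher by 1.22 ± 0.20 (adjusted p = 0.00258) and the value of TCL1A was -1.38 ± 0.25 (adjusted p = 0.00467). Without shCREM hairpin B these were 0.76 and -0.89 log2. DDB2, a p53 target of DNA repair, rose by 1.15 ± 0.24 log2 under shMBD2 (adjusted p = 0.0157), and RBBP4, a NuRD subunit, by 0.67 ± 0.17 (adjusted p = 0.0452, higher on 4 of 4 arrays). DDB2 lost its call without shMBD2_A replicate 2, shMBD2_C replicate 1 or shNTC replicate 1, RBBP4 without any 1 of these, the other 2 shMBD2 arrays or the shMS4A1 arrays, and HSPH1 without shCREM hairpin A (adjusted p = 0.0519). Of 12 measured genes with promoters known to be methylated outside the testis, 0 passed under shMBD2 (limma, 2395 of all genes at an unadjusted p under 0.05), with a median of 0.05 log2 (camera adjusted p = 0.935).

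A hypothesis tested here is that loss of CD20 and loss of MBD2 lower a shared set of genes. These comparisons use different control arrays, but share the shNTC hairpin and 1 limma fit with its spread, so the lists are not independent. Of 22 genes that fell under shMS4A1 and 179 under shMBD2, 4 fell under both (BCL2, CCR7, RGS1 and SLAMF1) against 0.287 from independent lists (Fisher's exact test p = 0.000171, with genes not independent), while 15 of the 22 had a lower value under shMBD2. With 1 array left out, a test chosen after seeing the data, the shared genes numbered 1 to 8 (Fisher's exact test p = 1.99e-06 to 0.0499). RGS1 was the only one without shMBD2_A replicate 2 (Fisher's exact test p = 0.0499) or shNTC replicate 1 (0.041). RGS1 and BCL2 were the only ones without shMBD2_A replicate 1 (Fisher's exact test p = 0.00186) or shMBD2_C replicate 2 (0.0027). There were 3 without shMBD2_C replicate 1 or shMS4A1 hairpins B or C, 4 without hairpin A or shNTC replicate 2, and 8 without shCREM hairpin A or B. Across all genes the changes correlated with r = 0.0373, and the overlap held in every case for RGS1 only. MS4A1 itself rose under shMBD2, so a lower MS4A1 level is not shared.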
